A study of Mus musculus with 9 samples.

How the data were processed

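RNA from primary mouse hepatocytes was sequenced in 9 libraries, 3 in each of 3 groups. The groups were wild-type cells with vehicle (WT DMSO), wild-type cells with tunicamycin (WT Tu), and cells lacking COX-2 in hepatocytes with tunicamycin (CKO Tu). Per the labels, cells were kept in 1% serum for 2 hours and then given DMSO or 6 μmol/L tunicamycin for 24 hours. Tunicamycin blocks the first step of protein N-glycosylation and so loads the endoplasmic reticulum (ER) with unfolded proteins.

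The deposited table holds FPKM, fragments per kilobase of gene length scaled to the size of the library, which the authors computed for 54532 genes. Per the submitters' processing notes, reads were aligned with HISAT2 2.2.1 to mm10 and assigned to genes with featureCounts 1.5.0-p3. The annotation release and the strand setting were not given in the sources used here. A table of counts was not used here. Each FPKM value times the gene's length was a whole multiple of 1 step per library, within a tolerance of 0.001 fragments, in 100% of libraries. Fragments per gene and the library size behind each FPKM value were recovered from that step. The recovered fragments came to between 14897358 and 16001484 per library. The library sizes behind the deposited FPKM were 0.948 to 1.07 times these totals, so a scaling factor per library had been applied.

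Genes with FPKM of at least 1 in at least 3 libraries were tested, 11858 in all. Values were taken as log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3, with all 9 libraries, a mean per group and an intensity trend in the spread. Tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method over the genes tested in each of 3 comparisons, with a threshold of 0.05. The pseudocount of 1 makes the fold change of genes with low FPKM smaller than the ratio of their means. Errors beside log2 changes are standard errors from limma, and errors beside FPKM values are standard deviations (SD) of 3 libraries. The labels do not say that the 3 replicates of a group came from separate animals, so the p-values measure the spread between these libraries.

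Gene lists were tested with camera in limma at a preset correlation between genes of 0.01, then with a correlation estimated from the data, and with fry. The 26 lists were PERK and ATF4 stress response, ER chaperones, XBP1 targets of ER-associated degradation and secretion, N-glycosylation, apoptosis, prostanoid pathway, mesenchymal genes and epithelial genes of epithelial-mesenchymal transition, hepatocyte secreted proteins and regulators, amino acid and urea metabolism with gluconeogenesis, cytochrome P450 and drug metabolism, bile acids, fatty acid oxidation, fatty acid synthesis, cholesterol synthesis, cytokines and NF-kB, acute phase, NRF2 and oxidative stress, autophagy and lysosome, cell cycle, oxidative phosphorylation, and markers of Kupffer cells, endothelial cells, stellate cells, cholangiocytes, and lymphocytes with neutrophils. The lists, tests, filters, first set of alternatives and the rule for named genes were set before the data were examined.

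Genes were named by that rule. They were Ptgs2 with 22 other genes chosen for ER stress, epithelial and mesenchymal state and hepatocyte state. To these were added, in the 2 main comparisons, the 10 genes with the largest change in each direction that had an adjusted p below the threshold, no overlap between the groups, a mean FPKM of at least 5 in the higher group and no predicted-gene or pseudogene symbol. From each list, up to 4 members with the largest change were taken, and 5 genes in each direction from those called in opposite directions in the 2 comparisons. Genes linked to or biased by sex, and Ftl1, Fth1, Gjb1, Cldn3 and Snai2, were added after their values were seen. Some members of the lists are not reported here.

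Ptgs2 failed the FPKM filter, so its fragments were compared by an exact two-sided permutation test, with a ratio and its 95% exact binomial interval. Against a group with 0 fragments, a fold was computed with 3 fragments over the group and given as a lower bound. Intervals and such bounds cover counting error only. Duplicate fragments could not be told from separate molecules.

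That first set was a pseudocount of 0.1, no filter on low values, a filter at FPKM of 5, upper-quartile scaling, quantile normalization, a fit to only the groups compared, the replicate number as a block, no intensity trend, a weight per library, a change of at least 1 on the log2 scale, and each library left out in turn. Added after seeing the data were voom on the recovered fragments, scaling to total fragments, removal of a lowess trend on GC content with a span of 0.3, and removal of sex-linked and sex-biased genes.

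The steps were tested on simulated data. For WT Tu against WT DMSO, 11617 genes were run and 194 of them were changed. Those changed by 0.5, 1 and 2 on the log2 scale were called in the right direction in 34.4%, 84.4% and 83.3% of cases. Of the unchanged genes, 0.07% were called. For CKO Tu against WT Tu, with 192 of 11658 genes changed, the shares were 53.2%, 81.8% and 93.8%, with 0.0785% of unchanged genes called. Far fewer genes were changed here than were called in the data, so these shares may not carry over. Simulated lists shifted by 0.3 were called in 100% of cases in both comparisons, and unshifted lists in 0% and 2%. Simulated genes varied independently. These rates therefore do not cover lists whose members vary together, such as the XBP1 targets with an estimated correlation of 0.33.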

Results

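Gene expression was measured in 9 libraries of primary mouse hepatocytes, 3 each from wild-type cells with vehicle (WT DMSO), wild-type cells with tunicamycin (WT Tu) and COX-2 knockout cells with tunicamycin (CKO Tu). Each library held between 14897358 and 16001484 assigned fragments, and between 11176 and 11324 genes had FPKM of at least 1. The first principal component held 51.4% of the variance and the second 23.2%. WT Tu replicate 1 stood apart from the other WT Tu libraries on the second component, at -36.6 against -19.6 for both others. Its share of mitochondrial fragments was 6.87%, the highest of the 9 libraries, against 5.25% and 5.9% in the other WT Tu libraries and 4.46% to 4.65% in the CKO Tu libraries.

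The series labels describe male mice in both genotypes. Xist, the transcript that silences an X chromosome in female cells, had between 20659 and 33657 fragments in each of the 6 WT libraries. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 fragments in all 6. In the CKO Tu libraries these 4 genes had 3633, 3489 and 3486 fragments, and Xist had 0, 3 and 0. Sex-linked transcription therefore separated the genotypes completely, and no sex pattern was present in both genotypes.

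**Figure D1:**
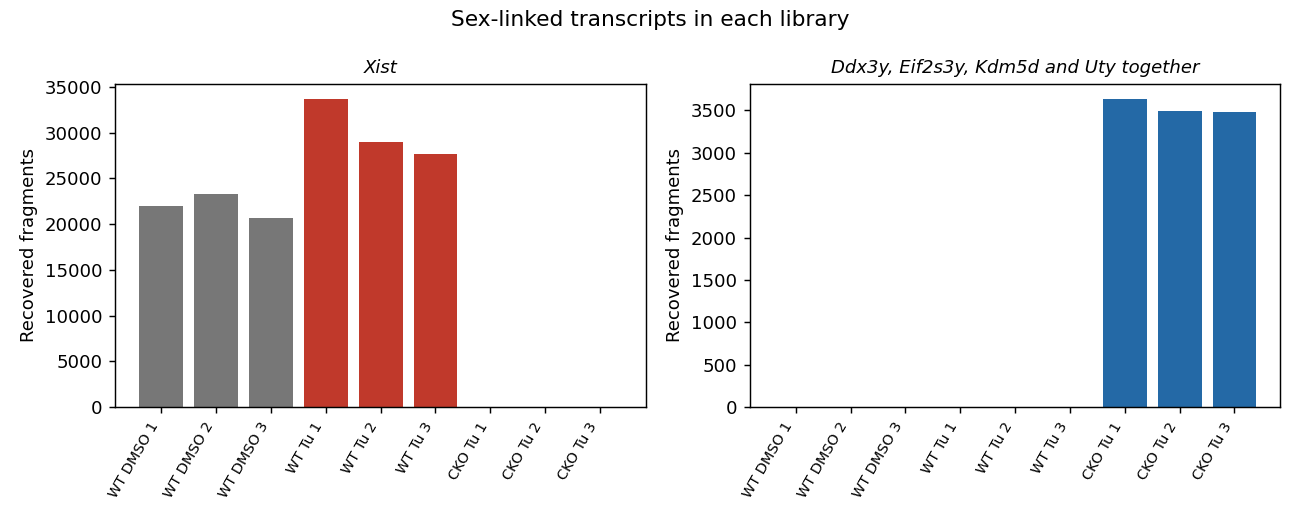
Recovered fragments of Xist (left) and of 4 Y-linked genes together (right) in each of the 9 libraries, 1 bar per library. Xist lies at 20659 or above in the WT libraries and at 3 or below in the CKO Tu libraries.

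The comparison of WT Tu with WT DMSO asks what ER stress does to normal hepatocytes. Genes for folding and clearing proteins in the ER rose steeply with tunicamycin. Hspa5, which encodes the main ER chaperone BiP (ENSMUSG00000026864, chromosome 2, 34771970 to 34777547, mm10), went from 576 ± 14.4 FPKM to 5312 ± 395 FPKM (SD, n = 3), a 9.22-fold rise (limma adjusted p = 1.8e-08). Hsp90b1, an ER chaperone of the HSP90 family, went from 75.5 ± 10.6 to 1786 ± 308 FPKM (SD, n = 3; limma adjusted p = 1.2e-07). Mesenchymal, epithelial, fatty acid synthesis and cytokine genes fell more often than they rose. These list calls were lost in the camera setting with an estimated correlation between genes (camera adjusted p = 0.078, 0.25, 0.19 and 0.25). Of 11858 genes tested with limma, 3981 changed, 2099 higher and 1882 lower in WT Tu.

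Among genes with no overlap between the groups and a mean FPKM of at least 5 in the higher group, the 10 largest rises were mostly in ER genes. Sdf2l1, Hsp90b1, Pdia4, Creld2, Manf and Hyou1, all ER folding factors, rose by 5.45, 4.54, 4.21, 3.99, 3.65 and 3.56 on the log2 scale, with standard errors (SE) of 0.06 to 0.13. Derl3, Herpud1 and Sel1l, which act in ER-associated degradation, rose by 4.65 ± 0.13, 4.62 ± 0.15 and 3.58 ± 0.09 (SE). Rny1, a small noncoding RNA, had 3 fragments in the WT DMSO group and 98 in the WT Tu group. Under the same limits the largest falls were in Ajuba (-2.15 ± 0.09), Ccl2 (-2.14 ± 0.14), Ces1b (-2.09 ± 0.16), Cyr61 (-2.05 ± 0.07), H6pd (-1.97 ± 0.12), Fgd3 (-1.92 ± 0.15), Tmem238 (-1.76 ± 0.20), Nid1 (-1.69 ± 0.06), Sorbs2 (-1.69 ± 0.11) and Cldn4 (-1.65 ± 0.28). Ajuba encodes a junction scaffold, Ccl2 a chemokine for monocytes, Cyr61 a matrix-associated signalling protein and Nid1 a basement membrane protein.

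**Figure D2:**
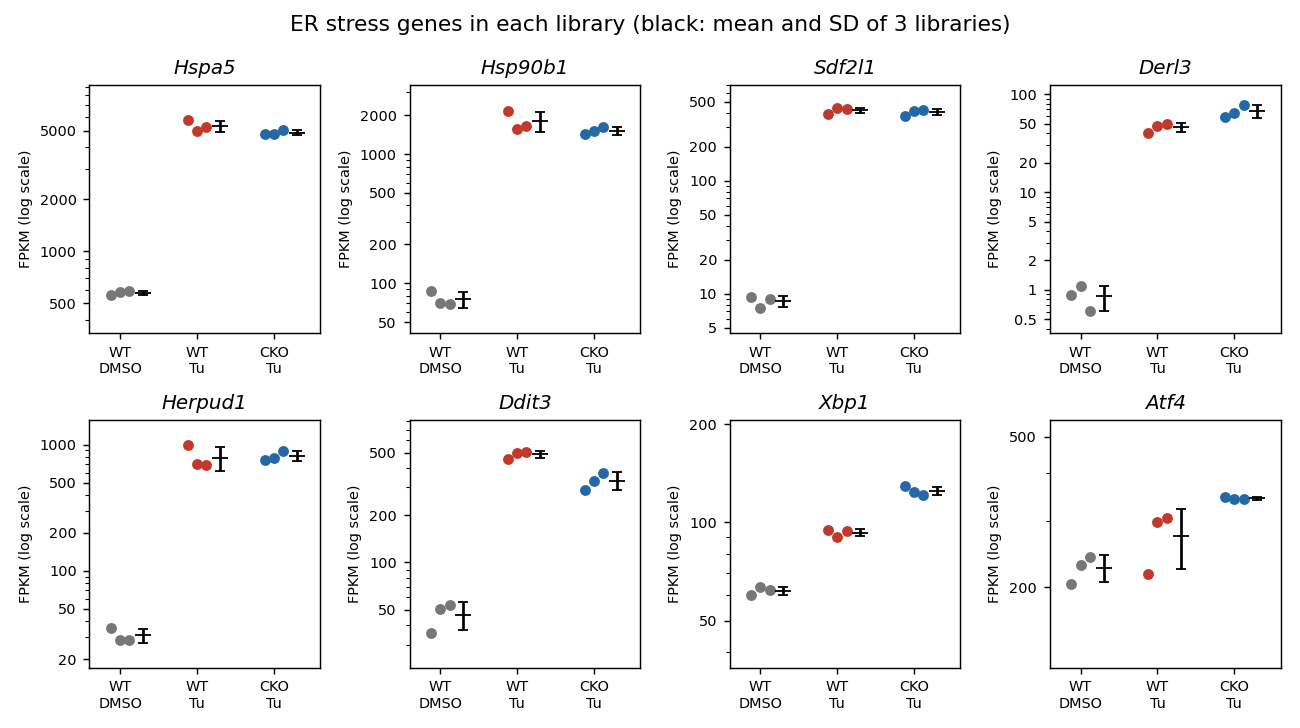
FPKM on a log scale for 8 ER stress genes, with 1 point per library in WT DMSO, WT Tu and CKO Tu, and the mean and SD of 3 libraries in black. Hspa5 lies at 576 in WT DMSO, 5312 in WT Tu and 4862 FPKM in CKO Tu on average.

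ER stress lists moved as groups. Of 20 ER chaperones, 19 rose, 0 fell and 1 did not pass (20 and 0 adjusted over the list alone), with a camera adjusted p = 6.2e-23, and adjusted p = 0.078 with an estimated correlation. Of 32 XBP1 targets, 30 rose, 0 fell and 2 did not pass (30 and 0 adjusted over the list alone), with a camera adjusted p = 6.8e-27, and adjusted p = 0.078 with an estimated correlation. Syvn1, a ubiquitin ligase of ER-associated degradation, rose by 2.79 ± 0.07, Dnajb9, a BiP cochaperone, by 2.43 ± 0.10, and Xbp1 itself by 0.58 ± 0.05 (SE). Of 31 N-glycosylation genes, 18 rose, 2 fell and 11 did not pass (19 and 3 adjusted over the list alone), with a camera adjusted p = 2.6e-07, and adjusted p = 0.25 with an estimated correlation. Gfpt1 and Uap1, enzymes that make the sugar donor UDP-GlcNAc, rose by 2.47 ± 0.10 and 1.31 ± 0.04, and Magt1, an oligosaccharyltransferase subunit, by 1.91 ± 0.08 (SE).

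The sensors and the PERK branch were mixed. Of 31 PERK and ATF4 genes, 10 rose, 4 fell and 17 did not pass (10 and 5 adjusted over the list alone), with a camera adjusted p = 0.18, which was 0.044 without WT Tu replicate 1, 0.031 without the filter and 0.0096 with the GC trend removed. Ddit3, which encodes the stress factor CHOP, rose from 46.4 ± 9.50 to 487 ± 26.6 FPKM (SD, n = 3; limma adjusted p = 9.4e-07). Atf3, Wars and Ppp1r15a rose by 1.75 ± 0.19, 1.47 ± 0.06 and 1.22 ± 0.12, and Trib3 by 0.30 ± 0.06 (SE). Trib3 did not pass under scaling to total fragments (limma adjusted p = 0.08). Eif2ak3, which encodes PERK, and Atf6 rose by 1.28 ± 0.07 and 1.26 ± 0.12 (SE). Ern1, which encodes IRE1, was at 47.2 ± 0.739 and 47.6 ± 1.08 FPKM (SD, n = 3; limma adjusted p = 0.84). Atf4 was at 224 ± 18.5 and 273 ± 49.1 FPKM (SD, n = 3; limma adjusted p = 0.13), and passed without WT Tu replicate 1 (limma adjusted p = 0.0018).

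Markers of endothelial cells fell with tunicamycin, and these levels stand beside the epithelial, mesenchymal and cytokine genes that follow. Of 6 endothelial markers tested, 0 rose, 5 fell and 1 did not pass (0 and 5 adjusted over the list alone), with a camera adjusted p = 0.00085, and adjusted p = 0.21 with an estimated correlation. Eng went from 2.71 ± 0.295 to 0.601 ± 0.0927 FPKM (SD, n = 3) and Stab1 from 2.39 ± 0.361 to 0.911 ± 0.0668 FPKM (SD, n = 3). Genes high in WT DMSO alone can pass the filter, which favours falls, and Eng and Stab1 averaged below 1 FPKM in WT Tu. The list did not pass without WT DMSO replicate 1, 2 or 3, with camera adjusted p of 0.27, 0.17 and 0.23. The filter was applied anew to the libraries left, which can drop such genes from the list. These values therefore do not tell the spread of replicates from a changed list. Of 2 Kupffer cell markers, 1 rose, 1 fell and 0 did not pass (1 and 1 adjusted over the list alone), with a camera adjusted p = 0.77, which was 0.012, lower in WT Tu, without the filter. The Kupffer cell markers Csf1r, Mpeg1 and Adgre1, below the filter, had 70, 125 and 24 fragments in WT DMSO and 24, 45 and 7 in WT Tu. Lyz2 fell by 1.11 and Cd68 rose by 0.37 ± 0.10 (SE), the latter a call lost without WT DMSO replicate 1 (limma adjusted p = 0.056) and without WT Tu replicate 2 or 3 (0.056 and 0.06). Of 4 cholangiocyte markers, 0 rose, 2 fell and 2 did not pass (0 and 3 adjusted over the list alone), with a camera adjusted p = 0.2, which was 0.043, lower in WT Tu, without the filter. Of 2 lymphocyte and neutrophil markers, 1 rose, 0 fell and 1 did not pass (1 and 0 adjusted over the list alone), among them Camp (1.83 ± 0.14), with a camera adjusted p = 0.18. Of 2 stellate cell markers, 0 rose, 0 fell and 2 did not pass (0 and 0 adjusted over the list alone), with Ecm1 at -0.16 ± 0.08 and Reln at -0.01 ± 0.12 (SE; camera adjusted p = 0.63).

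Mesenchymal and epithelial genes both fell more often than they rose. Of 16 mesenchymal genes, 1 rose, 10 fell and 5 did not pass (1 and 10 adjusted over the list alone), with a camera adjusted p = 0.00084, and adjusted p = 0.078 with an estimated correlation. Fn1, which encodes fibronectin, went from 56.8 ± 9.08 to 18.7 ± 1.86 FPKM, and Vim, which encodes vimentin, from 13.9 ± 0.834 to 6.50 ± 0.842 FPKM (SD, n = 3). Ctgf and Tgfb2 changed by -1.79 ± 0.11 and -0.92 ± 0.08, and Cdh2, which encodes N-cadherin, by -0.37 ± 0.07 (SE). Snai2, a transcription factor of mesenchymal transition, was the 1 that rose, by 0.70 ± 0.17 (SE), a call lost without WT DMSO replicate 1 (limma adjusted p = 0.052). Of 24 epithelial genes, 1 rose, 12 fell and 11 did not pass (1 and 16 adjusted over the list alone), with a camera adjusted p = 0.00028, and adjusted p = 0.25 with an estimated correlation. Cdh1, which encodes E-cadherin, went from 23.4 ± 2.71 to 15.9 ± 1.65 FPKM (SD, n = 3), and the junction genes Cgn, Cldn3 and Gjb1 changed by -1.23 ± 0.12, -1.23 ± 0.09 and -0.72 ± 0.15 (SE). Snai1, Acta2 and Tgfb1 were below the filter, at 45, 3 and 74 fragments in WT DMSO and 77, 7 and 31 in WT Tu.

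Among genes of hepatocyte function, of 34 hepatocyte genes, 2 rose, 11 fell and 21 did not pass (2 and 12 adjusted over the list alone), with a camera adjusted p = 0.046, and adjusted p = 0.58 with an estimated correlation. That call was lost without WT DMSO replicate 2 or 3 (camera adjusted p = 0.13 and 0.16), without WT Tu replicate 1 or 2 (0.066 and 0.062), with the GC trend removed (0.14), with the filter at FPKM of 5 (0.062), with only the 2 groups compared (0.063) and with no intensity trend (0.053). Hnf4a and Cebpa, regulators of hepatocyte identity, changed by -0.72 ± 0.09 and -1.15 ± 0.18, and Alb, which encodes albumin, by -0.01 ± 0.07 (SE; limma adjusted p = 0.9). Of 32 amino acid, urea and gluconeogenesis genes, 4 rose, 4 fell and 24 did not pass (4 and 4 adjusted over the list alone), with a camera adjusted p = 0.92. Examples were Oat (1.46 ± 0.08) and Pck2 (-0.66 ± 0.08). Their median change was -0.02 and their mean 0.05 on the log2 scale. Of 35 cytochrome P450 and drug metabolism genes, 5 rose, 6 fell and 24 did not pass (5 and 6 adjusted over the list alone), with a camera adjusted p = 0.38. Examples were Cyp1a2 (-0.87 ± 0.12) and Cyp2b10 (0.56 ± 0.08). Of 18 bile acid genes, 4 rose, 2 fell and 12 did not pass (4 and 2 adjusted over the list alone), with a camera adjusted p = 0.47. Examples were Acox2 (0.70 ± 0.08) and Abcc3 (-0.67 ± 0.07).

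Among lipid genes, of 25 fatty acid synthesis genes, 2 rose, 11 fell and 12 did not pass (2 and 12 adjusted over the list alone), with a camera adjusted p = 0.003, and adjusted p = 0.19 with an estimated correlation. Dgat2 and Gpam, enzymes of triglyceride synthesis, changed by -0.99 ± 0.18 and -0.95 ± 0.07 (SE). Of 28 fatty acid oxidation genes, 4 rose, 4 fell and 20 did not pass (4 and 4 adjusted over the list alone), with a camera adjusted p = 0.92. Examples were Pdk4 (1.14 ± 0.10) and Cpt1a (0.49 ± 0.08). Of 24 cholesterol synthesis genes, 6 rose, 10 fell and 8 did not pass (7 and 10 adjusted over the list alone), with a camera adjusted p = 0.22. Mvd rose by 1.30 ± 0.12 (SE).

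Among stress and defence genes, of 19 cytokine and NF-kB genes, 0 rose, 9 fell and 10 did not pass (1 and 9 adjusted over the list alone), with a camera adjusted p = 0.0011, and adjusted p = 0.25 with an estimated correlation. Ccl2 and Cxcl1, both chemokines, changed by -2.14 ± 0.14 and -1.49 ± 0.12 (SE). Of 31 NRF2 genes, 1 rose, 12 fell and 18 did not pass (1 and 13 adjusted over the list alone), with a camera adjusted p = 0.00085, and adjusted p = 0.26 with an estimated correlation. Osgin1 and Txnrd1 changed by -1.05 ± 0.10 and -0.62 ± 0.07 (SE). Of 25 acute phase genes, 5 rose, 3 fell and 17 did not pass (5 and 3 adjusted over the list alone), with a camera adjusted p = 0.94. Examples were Il1rn (0.60 ± 0.10) and Itih4 (-0.54 ± 0.07). Their median change was -0.01 and their mean -0.02 on the log2 scale, while camera ranked them upward. Of 25 apoptosis genes, 2 rose, 8 fell and 15 did not pass (3 and 8 adjusted over the list alone), with a camera adjusted p = 0.22. Examples were Bcl2l1 (-0.95 ± 0.17) and Cflar (0.66 ± 0.06), both inhibitors of cell death.

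Of 26 autophagy and lysosome genes, 10 rose, 5 fell and 11 did not pass (12 and 6 adjusted over the list alone), with a camera adjusted p = 0.17, which was 0.029, higher in WT Tu, without the filter. Examples were Atg12 (0.61 ± 0.06) and the ER autophagy receptor Retreg1 (1.19 ± 0.15). Of 16 cell cycle genes, 2 rose, 5 fell and 9 did not pass (2 and 5 adjusted over the list alone), with a camera adjusted p = 0.22. Examples were Ccne2 (0.93 ± 0.13) and Mcm5 (-0.64 ± 0.12). Of 34 oxidative phosphorylation genes, 1 rose, 5 fell and 28 did not pass (1 and 5 adjusted over the list alone), with a camera adjusted p = 0.15 as deposited, 0.04 without the filter, 0.037 with upper-quartile scaling, 0.0025 with quantile normalization and 0.0092 with total-fragment scaling. Examples were Ndufa9 (-0.79 ± 0.06) and Cyc1 (-0.44 ± 0.08). Of 9 prostanoid genes, 2 rose, 1 fell and 6 did not pass (2 and 2 adjusted over the list alone), with a camera adjusted p = 0.57. Examples were Tbxa2r (0.52 ± 0.11) and Ptges2 (-0.47 ± 0.10). Ptgs1 and Ptger4 were below the filter, at 23 and 62 fragments in WT DMSO and 16 and 40 in WT Tu.

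**Figure D3:**
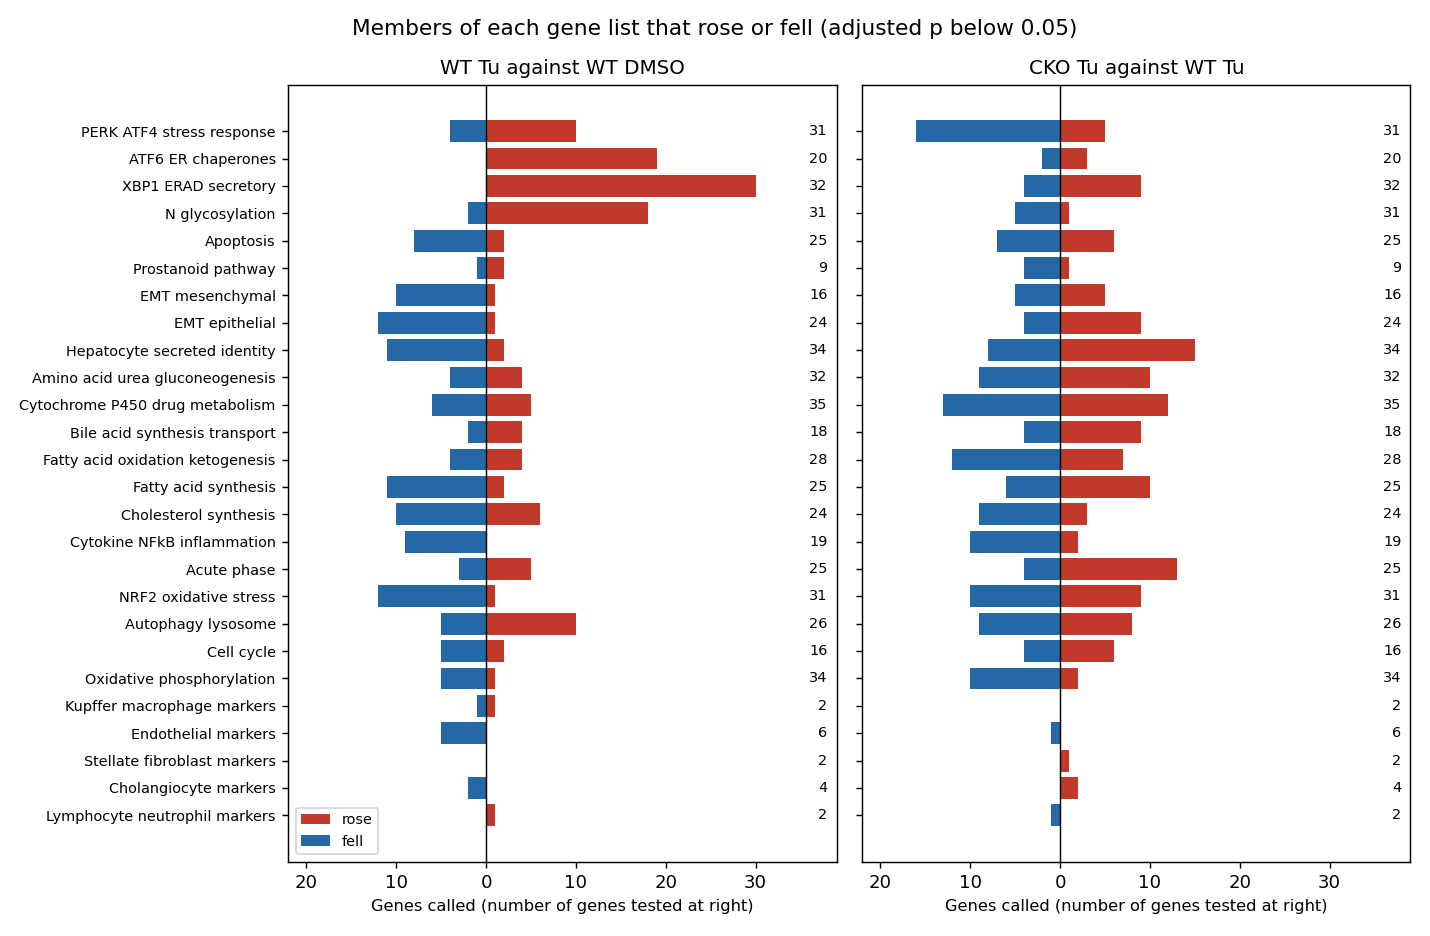
Number of genes in each of 26 lists that rose (right of 0) or fell (left of 0) in WT Tu against WT DMSO and in CKO Tu against WT Tu, with the number tested at the right edge. In the first comparison 30 of 32 XBP1 targets rose.

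By camera 10 of the 26 lists passed in WT Tu against WT DMSO, 3 higher and 7 lower, and 0 passed with an estimated correlation, where 5 had an unadjusted p below 0.05. The mesenchymal list lost its call at an estimated correlation of -0.0074, below the preset 0.01. That setting therefore changes more than the correlation, and lost calls cannot be put down to members varying together. In the same comparison 376 of the 3981 changed genes had a change of at least 1 on the log2 scale, 277 higher and 99 lower. The groups did not overlap in 5541 genes (46.7%), where chance gives 10%. Scaling to total fragments put the median change of all genes at -0.108 on the log2 scale and gave 1430 genes higher and 3108 lower (31.5% higher), and upper-quartile scaling gave 1739 and 2375 (42.3% higher), beside 52.7% higher as deposited. Fold changes fell with the GC content of genes, with a Spearman correlation of -0.345 across genes, which are not independent replicates.

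The comparison of CKO Tu with WT Tu sets cells lacking COX-2 beside wild-type cells under ER stress, in libraries that also differ in sex-linked transcripts. Ptgs2, which encodes COX-2 (ENSMUSG00000032487, chromosome 1, 150100031 to 150108227, mm10), was barely expressed. It had 0, 13 and 8 fragments in WT DMSO, 8, 5 and 5 in WT Tu, and 1, 1 and 2 in CKO Tu. CKO Tu held 0.214 of the WT Tu level (95% interval 0.0527 to 0.65), with an exact permutation p = 0.1, the smallest that 3 against 3 can give. WT Tu held 0.924 of the WT DMSO level (95% interval 0.464 to 1.82; exact permutation p = 1). The labels do not say which exons were deleted, and a gene total can hold fragments from the rest of the gene.

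The largest differences between CKO Tu and WT Tu were in sex-linked and sex-biased genes. Major urinary protein genes, which male mouse liver expresses highly, were higher in CKO Tu. Mup7 was at 0.130 ± 0.174 FPKM in WT Tu and 1780 ± 157 FPKM in CKO Tu (SD, n = 3; limma adjusted p = 5.4e-10). Cyp2a4, a steroid hydroxylase more abundant in female liver, went from 137 ± 21.9 to 0.112 ± 0.00154 FPKM (SD, n = 3; limma adjusted p = 1e-09). Of 42 sex-biased genes tested, listed after some values had been seen, 41 were called, all 41 in the direction of a male pattern in CKO Tu. Of 11858 genes tested with limma, 4538 changed, 2213 higher and 2325 lower in CKO Tu (48.8% higher), and scaling to total fragments gave 2597 higher and 1880 lower (58% higher).

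Of the 20 genes with the largest differences, 10 in each direction under the limits given above, 17 were in the sex lists. Higher in CKO Tu were Mup7 (10.63 ± 0.14), Mup12 (9.89 ± 0.09), Serpina1e (5.0 ± 0.13), Mup21 (4.94 ± 0.21), Mup20 (4.92 ± 0.22), Mup11 (4.87 ± 0.07), Hamp (4.42 ± 0.34) and Cyp2d9 (3.77 ± 0.12). Ddx3y and Eif2s3y, with 0 fragments in WT Tu, were at least 1850-fold and 779-fold higher. Lower in CKO Tu were Cyp2a4 (-6.94 ± 0.11), Cyp2c69 (-4.20 ± 0.11), Cyp2c40 (-3.63 ± 0.10), Cyp2b10 (-3.28 ± 0.08) and Il23a (-2.76 ± 0.30). Cyp2b9 and Sult2a1, with 0 fragments in CKO Tu, were at least 508-fold and 119-fold lower. Xist, Sult2a2 and Cyp3a44 had 90181, 448 and 607 fragments in WT Tu and 3, 1 and 1 in CKO Tu. Hamp, which encodes the iron hormone hepcidin, Cyp2b10 and Il23a were the 3 outside the sex lists. Absence from these lists does not show that a gene is free of sex bias. Cyp2b9 and Cyp2b13, of the same family as Cyp2b10, are in the female list. Counts of X-linked or sex-biased members given below take only listed genes and genes on the X and Y chromosomes. The Mup, Serpina1, Cyp2a, Cyp2b, Cyp2c, Cyp3a and Sult2a genes belong to families with near-identical members, so fragments of single members are uncertain.

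Few ER chaperones passed between the genotypes under tunicamycin. Hspa5 was at 5312 ± 395 FPKM in WT Tu and 4862 ± 153 FPKM in CKO Tu (SD, n = 3; limma adjusted p = 0.17), and Hsp90b1 at 1786 ± 308 and 1512 ± 104 FPKM (SD, n = 3; limma adjusted p = 0.21). Under quantile normalization Hspa5 was higher in CKO Tu (0.27 on the log2 scale, limma adjusted p = 0.0029). Of 20 ER chaperones, 3 rose, 2 fell and 15 did not pass (2 and 2 adjusted over the list alone), with a camera adjusted p = 0.86. Examples were Dnajb11 (0.40 ± 0.08) and P4hb (0.33 ± 0.05), the latter a call lost under quantile normalization (0.012 on the log2 scale, limma adjusted p = 0.88). The median of the chaperones was -0.01 and the mean 0.03 on the log2 scale. Of 32 XBP1 targets, 9 rose, 4 fell and 19 did not pass (10 and 4 adjusted over the list alone), with a camera adjusted p = 0.42. Examples were Derl3 (0.53 ± 0.13), Xbp1 (0.42 ± 0.05) and Dnajb9 (-0.47 ± 0.10), with the Derl3 call lost at a pseudocount of 0.1 (limma adjusted p = 0.051). Of 31 N-glycosylation genes, 2 of them X-linked or sex-biased, 1 rose, 5 fell and 25 did not pass (1 and 3 adjusted over the list alone), with a camera adjusted p = 0.55. Examples were Srd5a3 (-0.45 ± 0.08) and Rpn1 (0.27 ± 0.06).

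More PERK and ATF4 genes fell than rose in CKO Tu. Of 31, 5 rose, 16 fell and 10 did not pass (6 and 16 adjusted over the list alone), with a camera adjusted p = 0.1, which was 0.049 without WT DMSO replicate 1 and 0.025 without WT Tu replicate 1. Gdf15 and Nupr1, stress-induced genes, fell by 1.28 and 0.97, and Ddit4 and Stc2 rose by 1.28 ± 0.15 and 1.02 ± 0.14 (SE). Ddit3 went from 487 ± 26.6 to 332 ± 42.1 FPKM (SD, n = 3; limma adjusted p = 0.017), a call lost without CKO Tu replicate 1 (limma adjusted p = 0.065) and without the filter (0.051). Eif2ak3 rose by 0.34 ± 0.07 (SE). Atf3, Trib3, Atf6 and Ern1 differed by -0.42 ± 0.19, -0.12 ± 0.06, -0.14 ± 0.12 and -0.01 ± 0.04 (SE) and did not pass. Atf3 passed without WT DMSO replicate 1 (limma adjusted p = 0.00054) and Trib3 without WT Tu replicate 1 (0.02). Atf4 differed by 0.35 ± 0.12 (SE; limma adjusted p = 0.053) and passed without WT Tu replicate 1, 2 or 3 (0.047, 0.046 and 0.033).

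Hepatocyte genes rose more often than they fell in CKO Tu, in libraries that also differed in sex-linked transcripts. Of 34, 2 of them X-linked or sex-biased, 15 rose, 8 fell and 11 did not pass (15 and 8 adjusted over the list alone), with a camera adjusted p = 0.1. Hnf4a went from 6.43 ± 0.779 to 19.8 ± 1.25 FPKM (SD, n = 3; limma adjusted p = 1e-05), and Apoa1 and Fga, which encode plasma proteins, rose by 1.77 ± 0.16 and 1.37 ± 0.16 (SE). Alb fell by 0.47 (limma adjusted p = 0.0011), a call lost without the filter (adjusted p = 0.49), where the change was again -0.473. The Alb call was also lost under quantile normalization, where the change was 0 on the log2 scale. That method gives a gene with the same rank in every library the same value, so this 0 is no separate evidence on Alb. Of 25 acute phase genes, 13 rose, 4 fell and 8 did not pass (13 and 6 adjusted over the list alone), with a camera adjusted p = 0.054 and adjusted p = 0.83 with an estimated correlation. Saa3 rose by 2.79 ± 0.10 and Hamp by 4.42 ± 0.34, and Il1rn fell by 1.98. The acute phase list passed without WT DMSO replicate 1 or 2 (camera adjusted p = 0.049 and 0.044), without WT Tu replicate 1 or 3 (0.016 and 0.032) and without CKO Tu replicate 1, 2 or 3 (0.039, 0.043 and 0.018).

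Of 32 amino acid, urea and gluconeogenesis genes, 1 of them X-linked or sex-biased, 10 rose, 9 fell and 13 did not pass (10 and 9 adjusted over the list alone), with a camera adjusted p = 0.55. Their median change was -0.02 and their mean 0.27 on the log2 scale. G6pc, Tat and Pck1, genes of glucose production and tyrosine breakdown, rose by 2.77 ± 0.10, 2.42 ± 0.15 and 1.54 ± 0.24 (SE). Of 35 cytochrome P450 and drug metabolism genes, 3 of them X-linked or sex-biased, 12 rose, 13 fell and 10 did not pass (12 and 13 adjusted over the list alone), with a camera adjusted p = 0.66. Examples were Cyp4a12a (3.0 ± 0.09) and Cyp2b10 (-3.28 ± 0.08). Their median change was 0.01 and their mean -0.26 on the log2 scale. Of 18 bile acid genes, 2 of them X-linked or sex-biased, 9 rose, 4 fell and 5 did not pass (9 and 4 adjusted over the list alone), with a camera adjusted p = 0.1. Examples were Cyp7b1 (3.30 ± 0.09) and Slco1a1 (1.80 ± 0.10), both in the male-biased list. Of 25 fatty acid synthesis genes, 10 rose, 6 fell and 9 did not pass (11 and 7 adjusted over the list alone), with a camera adjusted p = 0.52. Examples were Thrsp (1.74 ± 0.08) and Plin2 (-1.01 ± 0.05). Of 28 fatty acid oxidation genes, 7 rose, 12 fell and 9 did not pass (8 and 13 adjusted over the list alone), with a camera adjusted p = 0.47. Examples were Fabp1 (1.63 ± 0.39) and Pdk4 (-0.92 ± 0.10). Of 24 cholesterol synthesis genes, 1 of them X-linked or sex-biased, 3 rose, 9 fell and 12 did not pass (3 and 9 adjusted over the list alone), with a camera adjusted p = 0.47. Examples were Stard4 (1.00 ± 0.14) and Idi1 (-0.80 ± 0.13).

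Epithelial and mesenchymal genes split. Cdh1 went from 15.9 ± 1.65 to 26.3 ± 3.56 FPKM (SD, n = 3; limma adjusted p = 0.0022). Fn1 went from 18.7 ± 1.86 to 43.9 ± 3.69 FPKM (SD, n = 3; limma adjusted p = 0.00016), and Cdh2 fell by 0.35 (limma adjusted p = 0.0037). Vim was at 6.50 ± 0.842 and 5.42 ± 1.43 FPKM (SD, n = 3; limma adjusted p = 0.23), and passed without CKO Tu replicate 2 (-0.41 on the log2 scale, limma adjusted p = 0.022). Of 24 epithelial genes, 2 of them X-linked or sex-biased, 9 rose, 4 fell and 11 did not pass (11 and 4 adjusted over the list alone), with a camera adjusted p = 0.1. Examples were Gjb1 (1.24 ± 0.15) and Cgn (-1.54 ± 0.12). Of 16 mesenchymal genes, 5 rose, 5 fell and 6 did not pass (5 and 5 adjusted over the list alone), with a camera adjusted p = 0.96. Sparc differed by -0.67 ± 0.14 (SE). On the log2 scale the median of the mesenchymal list was -0.04 and its mean 0.10. Snai2 rose by 0.68 ± 0.17 (SE), a call lost without CKO Tu replicate 2 (limma adjusted p = 0.053). Snai1, Acta2 and Tgfb1, below the filter, had 67, 4 and 45 fragments in CKO Tu.

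**Figure D4:**
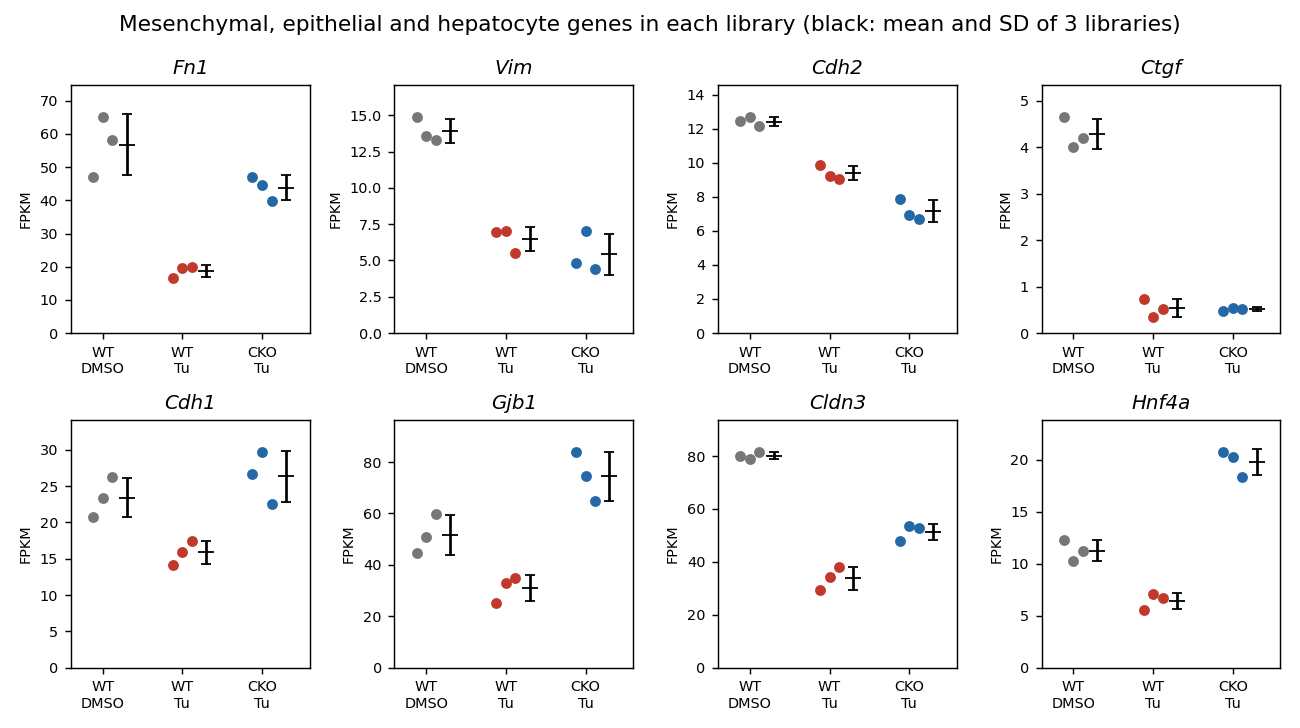
FPKM of 8 mesenchymal, epithelial and hepatocyte genes, with 1 point per library in WT DMSO, WT Tu and CKO Tu, and the mean and SD of 3 libraries in black. Ctgf, Gjb1 and Cldn3 were chosen from the lists after their values were seen.

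Inflammatory genes fell more often than they rose. Of 19 cytokine and NF-kB genes, 2 rose, 10 fell and 7 did not pass (2 and 10 adjusted over the list alone), with a camera adjusted p = 0.1, which was 0.049 without WT DMSO replicate 1. The chemokine genes Cxcl2, Ccl5 and Cxcl1 changed by -2.72 ± 0.24, -1.87 ± 0.20 and -1.17 ± 0.12 (SE). Of 31 NRF2 genes, 2 of them X-linked or sex-biased, 9 rose, 10 fell and 12 did not pass (10 and 10 adjusted over the list alone), with a camera adjusted p = 0.68. Examples were Hmox1 (1.46 ± 0.17) and Osgin1 (-1.32 ± 0.10). Of 25 apoptosis genes, 1 of them X-linked or sex-biased, 6 rose, 7 fell and 12 did not pass (6 and 8 adjusted over the list alone), with a camera adjusted p = 0.97. Examples were Fas (1.12 ± 0.15) and Map3k5 (0.90 ± 0.09). For the apoptosis list the median was -0.03 and the mean 0.06 on the log2 scale. Of 26 autophagy and lysosome genes, 1 of them X-linked or sex-biased, 8 rose, 9 fell and 9 did not pass (8 and 10 adjusted over the list alone), with a camera adjusted p = 0.74. Examples were Ulk1 (1.17 ± 0.11) and Sqstm1 (-0.67 ± 0.05). Of 16 cell cycle genes, 6 rose, 4 fell and 6 did not pass (6 and 4 adjusted over the list alone), with a camera adjusted p = 0.55. Examples were Ccne1 (1.14 ± 0.13) and Mcm6 (1.00 ± 0.07). Of 34 oxidative phosphorylation genes, 1 of them X-linked or sex-biased, 2 rose, 10 fell and 22 did not pass (2 and 10 adjusted over the list alone), with a camera adjusted p = 0.1, which was 0.016 without WT Tu replicate 1. Examples were Ndufa10 (-0.47 ± 0.06) and Uqcrc1 (-0.41 ± 0.04).

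Of 9 prostanoid genes, 1 rose, 4 fell and 4 did not pass (2 and 4 adjusted over the list alone), with a camera adjusted p = 0.36. Examples were the prostanoid transporter Abcc4 (-1.60 ± 0.09) and the prostaglandin E synthase Ptges (0.97 ± 0.13). Ptgs1 and Ptger4, below the filter, had 24 and 111 fragments in CKO Tu. Of 6 endothelial markers, 0 rose, 1 fell and 5 did not pass (0 and 1 adjusted over the list alone), with a camera adjusted p = 0.7, among them Pecam1 (-0.46 ± 0.10). Of 2 Kupffer cell markers, 0 rose, 0 fell and 2 did not pass (0 and 0 adjusted over the list alone), with Cd68 at -0.09 ± 0.10 and Lyz2 at 0.02 ± 0.15 (camera adjusted p = 0.89). Of 4 cholangiocyte markers, 2 rose, 0 fell and 2 did not pass (2 and 0 adjusted over the list alone), with a camera adjusted p = 0.23. Spp1 rose by 0.68 ± 0.08 and Sox9 by 0.51 ± 0.17 (SE), the latter a call lost without WT DMSO replicate 3 (limma adjusted p = 0.052), WT Tu replicate 1 (0.077) and CKO Tu replicate 1, 2 or 3 (0.093, 0.11 and 0.059). Of 2 stellate cell markers, 1 rose, 0 fell and 1 did not pass (1 and 0 adjusted over the list alone), among them Reln (1.37 ± 0.12), with a camera adjusted p = 0.42. Of 2 lymphocyte and neutrophil markers, 0 rose, 1 fell and 1 did not pass (0 and 1 adjusted over the list alone), with a camera adjusted p = 0.67. Camp fell by 0.54, a call lost without WT Tu replicate 3 (limma adjusted p = 0.052) and CKO Tu replicate 1 or 2 (0.052 and 0.051).

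In CKO Tu against WT Tu, 437 genes had a change of at least 1 on the log2 scale, 266 higher and 171 lower. The groups did not overlap in 6069 genes (51.2%), where chance gives 10%. By camera 0 of the 26 lists passed and 7 had an unadjusted p below 0.05, while fry, which tests a list without setting it against other genes, called 13. With an estimated correlation 0 lists passed, and the smallest camera adjusted p was 0.8. Without the filter 6 lists passed, the PERK and ATF4, cytokine and oxidative phosphorylation lists lower (camera adjusted p = 0.0057 each) and the hepatocyte, bile acid and acute phase lists higher (0.006, 0.0074 and 0.0049). Without the X and Y chromosomes and the listed sex-biased genes, 394 tested genes in all, 4366 genes were called, 2128 higher and 2238 lower.

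Genes that changed with tunicamycin in wild-type cells often lay the opposite way in CKO Tu against WT Tu. Higher in WT Tu and then lower in CKO Tu were Ddit3, Il23a, Mfsd2a, Atp13a4 and Xist. Mfsd2a, a lipid transporter, went from 12.8 ± 0.981 to 55.7 ± 2.06 and 28.2 ± 2.26 FPKM, and Il23a, a cytokine subunit, from 2.98 ± 1.47 to 20.3 ± 3.63 and 2.19 ± 0.948 FPKM in the order WT DMSO, WT Tu, CKO Tu (SD, n = 3). Lower in WT Tu and then higher in CKO Tu were Fn1, H6pd, Ces1b, Apobec1 and Ugt2b35. H6pd, an ER enzyme that makes NADPH, went from 33.9 ± 6.49 to 7.87 ± 0.905 and 21.2 ± 0.221 FPKM (SD, n = 3). In all, 1133 genes were called in opposite directions, 578 higher and 555 lower with tunicamycin, and 731 in the same direction. Independent calls would give 763 opposite and 761 in the same direction. Both comparisons share the WT Tu libraries, which by itself favours opposite changes, and the WT and CKO libraries also differ in sex-linked transcripts.

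The comparison of CKO Tu with WT DMSO joins genotype and treatment, since no CKO cells with DMSO were used here. Hspa5 rose by 3.07 ± 0.07, Sdf2l1 by 5.39 ± 0.09, Derl3 by 5.18 ± 0.13 and Ddit3 by 2.83 ± 0.15 (SE). Vim fell by 1.24 and Fn1 by 0.36, Hnf4a rose by 0.76 ± 0.09, and Cdh1 differed by 0.16 ± 0.12 (SE; limma adjusted p = 0.3). In all 5869 genes changed, 3001 higher and 2868 lower (51.1% higher), 857 of them by at least 1 on the log2 scale. Upper-quartile scaling gave 2526 higher and 3437 lower (42.4% higher), and scaling to total fragments 2552 and 3426 (42.7% higher). Whether tunicamycin acts differently in CKO cells was not tested, because that needs CKO cells with DMSO.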

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

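Tests with voom on recovered fragments, total-fragment scaling, removal of the GC trend and removal of sex-linked and sex-biased genes were chosen after the results were seen. The 3 counts of changed genes and the count of opposite calls stayed within 1.5 times under 22 alternatives. With each library left out in turn, the counts ran from 2973 to 3815 for WT Tu against WT DMSO, from 3326 to 4833 for CKO Tu against WT Tu, and from 4862 to 6662 for CKO Tu against WT DMSO. The opposite calls ran from 779 to 1378 over all alternatives. Asking for a change of at least 1 on the log2 scale left 376, 437 and 857 genes, by construction. The count of lists in WT Tu against WT DMSO went from 10 to 0 with an estimated correlation between genes, where the smallest camera adjusted p was 0.078 and 5 lists had an unadjusted p below 0.05, and to 15 without the filter; the other alternatives gave from 8 to 11. In CKO Tu against WT Tu the count of lists went from 0 to 6 without the filter, to 1 with upper-quartile scaling, 1 with quantile normalization, 3 with only the 2 groups compared, 3 with library weights, 1 with voom, 2 with total-fragment scaling and 1 without sex-linked and sex-biased genes; leaving out single libraries gave from 0 to 3, and the cause was not tested. Acute phase genes were called in 15 of 24 alternatives, with adjusted p from 0.0049 to 0.83. The Ptgs2 difference was -0.095 on the log2 scale and -0.657 with a pseudocount of 0.1, because the smaller pseudocount widens differences between low values. Of 464 results for named genes under 9832 runs, 9477 kept their direction and side of the threshold, 254 lost their call, 99 gained one and 2 reversed. Many named genes were picked for a large change, which favours keeping a call. Over all genes in WT Tu against WT DMSO, the fewest of the 3981 calls kept were 2897, without WT DMSO replicate 3, with 0 reversed. Hspa5 in CKO Tu against WT Tu was 0.274 under quantile normalization, and Atp5d in that comparison was -0.171 without WT Tu replicate 1, with a range of -0.171 to 0.205 over the libraries left out; the cause was not tested. With the replicate number as a replicate block the counts were 3696, 4248 and 5683 genes, 988 opposite calls, and 10 and 0 lists. Libraries with the same number did not deviate together (correlations from -0.097 to 0.021). Ptgs2 has no value under alternatives that need it past the filter. At 14897358 to 16001484 fragments per library, genes with few fragments, such as Ptgs2 with 18 in WT Tu, allow only wide intervals.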

Other observations

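Tests on single libraries exchanged between genotypes, on Y-linked fragments in WT libraries and on the genes called outside the sex lists were chosen only after the result was seen, and the YAP/TEAD list was written after 5 of its genes had been seen.

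Targets of YAP and TEAD, the transcription factors of the Hippo pathway, fell more often than they rose with tunicamycin. Of 17 tested, 12 fell and 1 rose in WT Tu against WT DMSO. Ctgf and Tgfb2 are also in the mesenchymal list. Camera p-values of the YAP/TEAD list were adjusted only over this list and the mitochondrial and iron lists below. Cyr61 went from 263 ± 11.1 to 62.9 ± 5.33 FPKM and Amotl2 from 16.5 ± 0.847 to 8.90 ± 0.447 FPKM (SD, n = 3). Among the 12 members not seen before listing, 7 fell and 1 rose (camera adjusted p = 0.0058, and unadjusted p = 0.018 with an estimated correlation). This fits a hypothesis of lower YAP/TEAD activity under tunicamycin that may be tested by other means. Of the 17 tested, Ankrd1, Ctgf, Igfbp3 and Fjx1 averaged 4.6, 4.29, 1.51 and 1.2 FPKM in WT DMSO and under 1 in both other groups. They passed the filter through WT DMSO, where they were high, which fixed their direction. The 12 falls of the 17 include theirs, which are no support for the hypothesis. The 7 falls and their p-values may include some of them. In CKO Tu against WT Tu 11 fell and 1 rose, and 7 and 1 of the 12 not seen before listing (camera adjusted p = 0.0034, and unadjusted p = 0.015 with an estimated correlation). Ptpn14 was the 1 that rose with tunicamycin, and Asap1 the 1 that rose in CKO Tu. Endothelial markers fell in the first comparison too, 5 of 6 tested, with Eng from 2.71 to 0.601 FPKM. Below the filter, Kdr, Flt4 and Fcgr2b went from 212, 305 and 200 to 48, 94 and 55 fragments. Tie1, Flt1, Stab2 and Lyve1 fell there as well, from 178, 51, 274 and 86 to 67, 10, 179 and 58 fragments. Gpr182, Dnase1l3, Tek and Bmp2 moved little or rose, from 78, 47, 188 and 40 to 69, 38, 212 and 43 fragments. A lower share of endothelial cells stays open as an untested source.

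Subunits encoded by mitochondrial DNA and genes of iron handling were listed after some of their values had been seen. Their camera p-values were adjusted only over these lists and the YAP/TEAD list, a milder correction than for the lists set beforehand. The adjusted values therefore cannot be set beside those of the earlier lists. For the 13 subunits in CKO Tu against WT Tu the unadjusted camera p was 0.0078. Of 13 mitochondrial subunits, 2 rose and 0 fell in WT Tu against WT DMSO (camera adjusted p = 0.063). That adjusted p was 0.049 with upper-quartile and 0.032 with total-fragment scaling, and 0.42 with the GC trend removed. In CKO Tu against WT Tu 0 rose and 7 fell (camera adjusted p = 0.012, and 0.054 under quantile normalization). With an estimated correlation the unadjusted camera p there was 0.27. Among the 8 subunits not seen before listing, 0 rose and 4 fell in that comparison (camera adjusted p = 0.072). Without WT Tu replicate 1, the library with the highest mitochondrial share (6.87%), the median of the 13 went from 0.33 to 0.22 in the first comparison (camera adjusted p = 0.25) and from -0.46 to -0.33 in the second (0.033). Of 20 iron genes, 3 rose and 3 fell in the first comparison and 5 rose and 7 fell in the second (camera adjusted p = 0.22 and 0.94). Fth1, which encodes ferritin heavy chain, was at 12430 ± 388 FPKM in WT Tu and 6860 ± 116 FPKM in CKO Tu (SD, n = 3; limma adjusted p = 1.4e-05), a call lost without the filter (-0.857 on the log2 scale, limma adjusted p = 0.12).

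Sex-linked transcripts separated all WT from all CKO libraries, although the labels describe male mice. Exchange of single libraries between genotypes would leave some library out of place within its genotype, and 0 libraries were. Loss of COX-2 in male cells as the source of the sex-linked transcripts is argued against, since male WT cells would hold Y-linked fragments, and the 6 WT libraries together held 0 where each CKO Tu library held at least 3486. Among called sex-biased genes not seen before listing, 100% moved in the direction of the bias (18 of 18, exact binomial p = 7.6e-06). That p-value takes the genes as independent, which genes of the same families in the same libraries are not. The direction of the 18 fits WT cells from female and CKO cells from male animals. For the 4366 genes called outside the sex lists, sex and genotype cannot be told apart, because no sex is present in both genotypes.

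Fold changes of WT Tu against WT DMSO fell with the GC content of genes. WT Tu replicate 1 as the whole source is argued against, since the rank correlation across genes was -0.233 without it. GC bias as the source of the ER response is argued against, since the 49 called members of the ER chaperone and XBP1 lists had a median change of 1.49 before and 1.53 after the GC trend was removed. Of 7 lists called lower, 6 stayed called after the trend was removed, and hepatocyte genes did not (adjusted p = 0.14). The median of that list was -0.12 (quartiles -0.33 and 0.02) before and -0.08 (-0.23 and 0.03) after, and its call, at adjusted p = 0.046, was also lost in settings that leave GC content as it is, such as no intensity trend (0.053), so these values do not decide on GC content for that list.

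Genes changed by tunicamycin lay the opposite way in CKO Tu against WT Tu in 1133 cases, against 731 the same way. With separate WT Tu libraries in each comparison, the mean covariance of the fold changes over 6 splits was -0.0104 (range -0.0186 to -0.00537), so the shared libraries alone are argued against. With the shared libraries the covariance was -0.0334, of which -0.023 came from the spread of the WT Tu libraries, so the counts of 1133 and 731 still carry the sharing. With separate libraries and the GC trend removed, the mean was -0.00837 and the highest -0.00592, which argues against GC content as well. A shift shared by all WT Tu libraries and the sex of the animals stay open as untested.

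For each comparison the 6 libraries give 10 splits into 3 and 3, too few for a share under 0.05. The real splits gave 3981, 4538 and 5869 genes, and the highest of the other splits gave 1, 1 and 1. In each comparison 1 split, the real one, gave as many genes. Every other split mixes libraries of both groups, so differences between the groups enter its spread. Its low count therefore sets no scale for chance.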
